A study of Homo sapiens with 16 samples.

How the data were processed

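CD4+ T cells, the helper lineage of T lymphocytes, were taken from blood of 16 children and profiled by ATAC-seq, in which the transposase Tn5 cuts and tags accessible DNA. Per the labels' protocols the cells were purified with a magnetic enrichment kit, the libraries were made with a Nextera kit, and they were sequenced on a HiSeq instrument. The labels place 6 libraries in healthy controls, 5 in children with active juvenile idiopathic arthritis (JIA) on treatment, and 5 in children in clinical remission on medication. JIA is the most common chronic arthritis of childhood. Each library is taken as 1 donor, since the labels give each a code of its own. Replicate numbers were assigned here in order of accession and pair no libraries.

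The submitters' processing notes name Bowtie2, SAMtools, bedtools and HTSeq, without versions, and the build hg19. The peak caller is not given in the sources used here, nor is any shift of reads for the position of Tn5, removal of duplicates or removal of mitochondrial reads. The authors deposited 3 kinds of file. The first is a list of gapped peaks per library, each with an open part, a flanking block on either side and the caller's own score, which is the authors' value and was used only to rank or filter peaks within a list. The second is 1 list of 248896 merged regions for the whole series, by its name merged from the top 100000 peaks of each library. The third is, per library, the deposited count of reads in each of 248860 of these regions. The 36 regions without a count all start at the first base of their contig. Per the file headers and messages of the count files, 92.4% to 96.4% of reads lacked a mate in the input, so mates were counted singly and a count is a read, not a fragment. The progress messages inside the count files were skipped. Rows for reads outside regions, of low mapping quality or not aligned were kept out of library sizes. In the median library, reads outside every region made up 36.4% of all reads, reads of low mapping quality 15.0% and reads not aligned 1.54%.

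The merged regions are much wider than single ATAC-seq peaks. The 236566 autosomal regions had a median width of 2730 bp, 33350 were wider than 10 kb, and together they covered 1898.3 Mb. A count therefore mixes accessible sites with the background around them. Regions of the sex chromosomes and unplaced contigs (12294) were left out of the main tests, because the sex of donors was not used.

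Counts were tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, TMM scaling, robust dispersion and 1 model of all 16 libraries with a 3-level group factor. filterByExpr with a minimum count of 10 removed 812 regions and left 235754. Regions with a Benjamini-Hochberg adjusted p under 0.05 were called. The contrasts were active vs healthy, remission vs healthy, active vs remission, and patients vs healthy, the last being the mean of both patient groups. Normalised CPM are counts per 1e6 counts of the TMM-scaled library size. The spread between donors was 18.8% (common biological coefficient of variation). The lowest chi-square per degree of freedom between replicates was 4.57, so no libraries were duplicates within sampling noise. The median count per region and library was 132. The pipeline was tested on simulated data with the real means, depths and dispersions, 235506 regions tested and 100 regions changed per fold and group. For active vs healthy it recovered 12% of regions changed 1.5-fold and 69% of those changed 2-fold, and for remission vs healthy the shares were also 12% and 69%. Beside these, 9 unchanged regions were called in active vs healthy and 11 in remission vs healthy. In both comparisons the share of false calls among all calls thus lay above the threshold of 0.05. The simulation has independent regions, which real libraries do not.

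Values of 1 number per library were compared by exact two-sided permutation tests of the difference of means, with 462 arrangements for 6 against 5 libraries, 252 for 5 against 5 and 8008 for 10 against 6. The smallest p that 6 against 5 can give is 0.00433. Benjamini-Hochberg adjustment ran over 18 of the measures computed per comparison, or over 22 chromosomes. Other measures, such as variants with other limits of width or distance, were left out of it and have no adjusted p. The overlap of peak sets was the Jaccard index of the open parts of the 100000 highest-scoring autosomal peaks of each pair of libraries, tested with 100000 permutations of the group labels. Recurrent high-scoring regions were the 13279 that held 1 of the 20000 highest-scoring peaks in at least 8 of the 16 libraries, without regard to group. Gene counts per chromosome (RefSeq) and GC content came from GRCh38 and no coordinate was carried between builds. The measures of wide and narrow regions, recurrent regions, chromosome ends, chromosome shares and mapping were chosen after seeing the data, so their p-values are descriptive. Peaks per library, their open width and the overlap of peak sets were fixed before the data were examined. For the flanks the share of peaks with flanking blocks had been fixed. That share was 100% in every library, and flank width is given in its place. All these measures were computed in Python 3.11.15 with SciPy.

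Regions named in the text followed a rule fixed before the data were examined. It takes the regions with the smallest p past the threshold in each direction, with the same sign in every fit that leaves out 1 library, up to 8 per direction for the comparisons of 1 patient group with healthy children and up to 5 for the rest. Where fewer than 3 pass, the 3 with the smallest p are named as not past the threshold. Gene-level tests, gene lists, motif sets, promoter shares, genomic classes and a GC correction had been planned, and were not computed, because the annotation and sequence used here are GRCh38 and the files are hg19. Regions are therefore given by hg19 position without a gene. The alternatives fixed with that rule were RLE size factors, library size only, loess offsets, DESeq2 1.42.0, limma-voom with sample quality weights (limma 3.58.1), no filter, a mean count of at least 30, only the groups compared, all chromosomes, 1 surrogate variable (sva 3.50.0) and leaving out each library. Alternatives added after seeing the data were lane as a block, regions with a recurrent high-scoring peak, regions of at most 10 kb, both limits together (3185 regions), the density of wide regions as a covariate, the densities of wide and recurrent regions as covariates in recurrent regions, and leaving out 3 libraries with under 0.1% of peaks at a score of 20 or more. The lane of each library was read from the 1 read name in its count file. These names place the libraries on 1 flow cell, with 2 libraries in each of 8 lanes. A library spread over several lanes would not be noticed, and all values by lane rest on this reading.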

Results

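Chromatin accessibility of blood CD4+ T cells was measured in 6 healthy children, 5 children with active JIA on treatment and 5 children in clinical remission on medication. The libraries held 61 to 176.2 reads counted in regions (in units of 1e6), with a median of 128.1. Depth was alike in the groups, at 115 ± 33 (SD, n = 6) in healthy, 121 ± 34 (n = 5) in active and 120 ± 43.8 (n = 5) in remission libraries. Between 51.5% and 63.16% of reads placed with sufficient quality fell in a region. Counts carry no molecular identifiers, so counting error understates the error of a count, and the spread between libraries was used throughout. All positions are hg19 and no annotation of that build was used, so no gene is given for a region.

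The number of called peaks and their shape were compared first, from the peak list that the authors made for each library. Peaks called on autosomes numbered, in units of 1e6, 1.16 ± 0.370 (SD, n = 6) in healthy, 1.18 ± 0.334 (n = 5) in active and 1.39 ± 0.375 (n = 5) in remission libraries. The open part of a peak had a median width of 788 bp ± 311 in healthy, 778 bp ± 468 in active and 760 bp ± 262 in remission libraries. The flanking blocks measured 510 bp ± 275, 476 bp ± 142 and 496 bp ± 376 in the same order. None of these differences exceeded the spread between libraries: the exact two-sided permutation p-values were 0.89, 0.329 and 0.349 for the number of peaks in active vs healthy, remission vs healthy and active vs remission. For open width the exact p-values were 0.976, 0.872 and 0.921, and for flank width 0.846, 0.924 and 0.976. In total the open parts covered 1570 Mb ± 879 (SD, n = 6) in healthy, 1410 Mb ± 939 (n = 5) in active and 1670 Mb ± 803 (n = 5) in remission libraries. Single libraries ranged from 287.6 Mb (remission 4) to 2374 Mb (active 5), so a called peak is not taken as a single accessible site. The 100000 highest-scoring peaks of 2 libraries overlapped with a mean Jaccard index of 24.5% within groups and 23.5% between groups (permutation p = 0.377). By group the mean was 30.76% within healthy, 19.68% within active and 19.91% within remission libraries, a contrast that was not tested. The overlap of single pairs ranged from 2.15% to 52.8%, so libraries of any group differed widely in peak calls. In 3 libraries, healthy 1, active 3 and remission 4, under 0.1% of peaks reached a score of 20. These libraries held 61, 71.1 and 86.3 reads in regions (in units of 1e6), below the median of 128.1. Low depth was not confined to them, since remission 1 held 66.9 and had 0.739% of peaks at that score or above.

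Active disease was compared with health to ask where CD4+ T-cell chromatin differed in children with active JIA on treatment. A region of 20310 bp on chromosome 10 (51937261 to 51957570) was lower in active libraries, with a log2 fold change of -3.36 (SE 0.45, edgeR adjusted p = 0.00214). Its normalised CPM were 0.436 ± 0.187 (SD, n = 6) in healthy and 0.0399 ± 0.018 (n = 5) in active libraries, and all 5 active libraries lay below every healthy one. The counts were small, at 28 to 77 per healthy and 2 to 9 per active library. No region passed in the other direction. The regions next in rank were not past the threshold, each with an edgeR adjusted p of 0.237. Higher values were found on chromosome 17 (38917813 to 38919112, log2 1.04, SE 0.2), chromosome 7 (155940561 to 155942810, log2 0.76, SE 0.15) and chromosome 5 (1236781 to 1246510, log2 0.64, SE 0.13). At each of them all 5 active libraries lay above every healthy one. The regions named here and below were picked for their small p, so a separation of the groups at them is no further support. Lower values were found on chromosome 6 (32632411 to 32638260, log2 -1.12, SE 0.2), in the segment that holds the major histocompatibility complex, where donors differ in sequence. A region of chromosome 7 (32944061 to 32948450) was also lower, at log2 -0.98 (SE 0.18). Below every healthy library lay 3 of 5 active libraries at the chromosome 6 region and 4 of 5 at this one.

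In active vs healthy, 1 of 235754 regions passed in edgeR and 26946 (11.43%) had an unadjusted p under 0.05. The count moved strongly with the method: DESeq2 called 3320 regions (145 higher, 3175 lower) and limma-voom with quality weights 264 (36 higher, 228 lower). The limma-voom fit changed the tool and weighted the libraries together, and these were not tested apart. For the chromosome 10 region DESeq2 gave log2 -3.42 (unadjusted p = 6.42e-14) but no adjusted p, so the region is not among its calls here. In the 27 alternatives that gave it an adjusted p (3.3e-05 to 0.23) that region kept its sign. For the 16 that leave out 1 library, the naming rule fixed the sign in advance. The region lost its call with library size alone as the scaling (adjusted p = 0.17) and with the density of wide regions as a covariate, added after seeing the data (adjusted p = 0.23). It was not among the regions tested, in any comparison, with a mean count of at least 30, with a width of at most 10 kb or with a recurrent high-scoring peak. A block for sequencing lane, added after seeing the data, gave 8408 calls (1590 higher, 6818 lower), and leaving out healthy 5 gave 1121 and leaving out active 3 gave 3. With library size alone as the scaling, the share of higher regions among those with an unadjusted p under 0.05 was 96.4% in place of 43.7%, no region passed, and the median region moved to log2 0.25.

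Remission was compared with health to ask what differed in treated children without active disease. The chromosome 10 region was lower here too, at log2 -3.43 (SE 0.47, edgeR adjusted p = 0.0031), with 0.0432 ± 0.0535 normalised CPM (SD, n = 5) and 0 to 10 counts per remission library. A region of 8330 bp near the end of chromosome 5 (780291 to 788620) was higher, at log2 1.28 (SE 0.19, edgeR adjusted p = 0.00672). Its normalised CPM were 1.19 ± 0.435 (n = 6) in healthy, 1.8 ± 0.174 (n = 5) in active and 2.83 ± 0.644 (n = 5) in remission libraries, and all 5 remission libraries lay above every healthy one. Not past the threshold were regions of chromosome 12 (132163117 to 132170836, log2 0.89, SE 0.16) and chromosome 5 (1236781 to 1246510, log2 0.72, SE 0.13), both with an edgeR adjusted p of 0.253. Lower values that did not pass were found on chromosome 9 (177805 to 180934, log2 -1.6, edgeR adjusted p = 0.475) and chromosome 7 (102304922 to 102330291, log2 -1.22, edgeR adjusted p = 0.875). In edgeR 1 region was higher and 1 lower, and 13031 had an unadjusted p under 0.05. DESeq2 called 4, among them the chromosome 10 region (DESeq2 adjusted p = 4.38e-08), limma-voom 2 and the lane block 2. Leaving out remission 2 gave 4 and leaving out remission 3 gave 1. Both edgeR calls were lost with library size alone as the scaling. The chromosome 5 call was also lost with 1 surrogate variable (edgeR adjusted p = 0.176), without remission 3 (0.0762), and in 3 alternatives added after seeing the data. The adjusted p of the chromosome 5 region ranged from 6.57e-05 to 0.721 over all alternatives.

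Active disease was then compared with remission among treated children. No region differed in edgeR, where 7180 regions (3.05%) had an unadjusted p under 0.05. The regions with the smallest p, all with an edgeR adjusted p of 1, were on chromosome 2 (68517741 to 68521090, log2 0.76, SE 0.17), chromosome 14 (65330411 to 65334500, log2 0.7, SE 0.16) and chromosome 5 (11192881 to 11193850, log2 0.97, SE 0.23) among the higher ones. Among the lower ones they were on chromosome 11 (89704656 to 89710345, log2 -3.61, SE 0.76), chromosome 7 (102117022 to 102120071, log2 -1.23, SE 0.27) and chromosome 5 (4285891 to 4287680, log2 -1.02, SE 0.23). The chromosome 11 region held only 0 to 4 counts per active library and 0 to 43 per remission library. DESeq2 called 1 region and limma-voom 0, and edgeR called 1 region without active 3 and 1 without remission 2. The lane block gave 1532 calls (38 higher, 1494 lower), in a fit over all 8 lanes, of which 2 hold a library of each group.

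All 10 patients together were compared with the 6 healthy children. The chromosome 10 region was lower at log2 -3.39 (SE 0.36, edgeR adjusted p = 7.11e-06), and 10 of 10 patient libraries lay below every healthy one. No other region passed. Higher values below the threshold were found on chromosome 5 at 1236781 to 1246510 (log2 0.68, SE 0.12, edgeR adjusted p = 0.132) and at 780291 to 788620 (log2 0.95, SE 0.17, adjusted p = 0.14), and on chromosome 7 at 155940561 to 155942810 (log2 0.74, SE 0.13, adjusted p = 0.174). Lower values below the threshold were found on chromosome 10 at 38640701 to 38648610 (log2 -0.73, SE 0.14, edgeR adjusted p = 0.174) and at 38944226 to 38950505 (log2 -0.65, SE 0.13, adjusted p = 0.33). In edgeR 26026 regions (11.04%) had an unadjusted p under 0.05. DESeq2 called 19 regions, among them the chromosome 10 region (DESeq2 adjusted p = 5.03e-15), limma-voom 4, and the lane block 562 (50 higher, 512 lower). Leaving out healthy 5 gave 24 calls, active 5 gave 4, remission 1 gave 3, and active 1, active 4, healthy 6 or remission 2 gave 2 each.

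**Figure D1:**
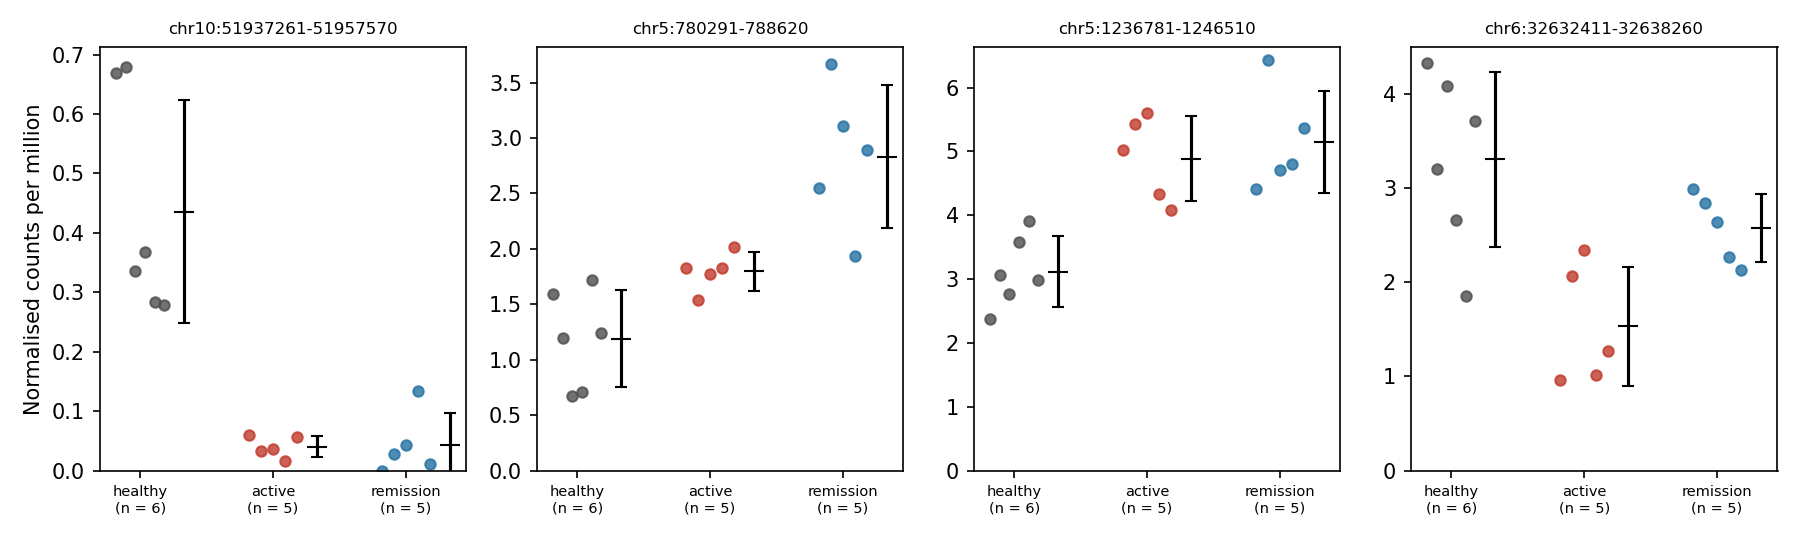
Normalised CPM (y axis) at 4 regions in 6 healthy, 5 active and 5 remission libraries; points are libraries, and the bar beside each group is the mean with SD. At chromosome 10 (51937261 to 51957570) all 10 patient libraries lay below every healthy one, and at chromosome 5 (780291 to 788620) all 5 remission libraries lay above every healthy one; the other 2 regions did not pass the threshold.

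The active and remission comparisons share their healthy libraries, so their fold changes are correlated even without an effect. Across regions, which are not independent replicates, the fold changes had r = 0.623, against 0.466 for simulated unchanged groups. The covariance was 0.035 against 0.019 in the simulation, a difference of 0.016. The simulations used here drew each region independently, without the variation that regions of real libraries share. Real unchanged groups could therefore exceed them, and the excess is not read as an effect shared by the patient groups. With the healthy libraries split 3 and 3, the correlation averaged 0.206 over 20 splits (-0.022 to 0.295) and the covariance 0.015. The chromosome 10 region was the 1 lower call shared by both edgeR comparisons. In 20 simulations of unchanged groups against the same healthy libraries 0 calls were shared (single comparisons gave 0 to 2 calls); independent lists, which leave out the shared libraries, would share 4.2e-06. In 5 of 20 splits of the healthy libraries a region was called on both sides with the same sign. Which region it was in each split was not recorded. The median number of shared calls over the splits was 0.

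Differences that were spread over many regions followed region width. In active vs healthy the median log2 fold change fell from 0.07 in the 33098 regions of up to 1 kb to -0.44 in the 1500 regions over 100 kb, which covered 619.9 Mb. The median over 100 kb was -0.26 in remission vs healthy, -0.19 in active vs remission and -0.35 in patients vs healthy. Regions with a recurrent high-scoring peak had a median of -0.26 in active vs healthy, -0.05 in remission vs healthy and -0.2 in active vs remission. These medians are over regions of the same libraries and carry no test. With library size alone as the scaling the wide-region medians were -0.19, -0.13 and -0.06 in active vs healthy, remission vs healthy and active vs remission, and loess offsets, which remove trends with abundance, gave 0.01, -0.01 and 0.02.

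**Figure D2:**
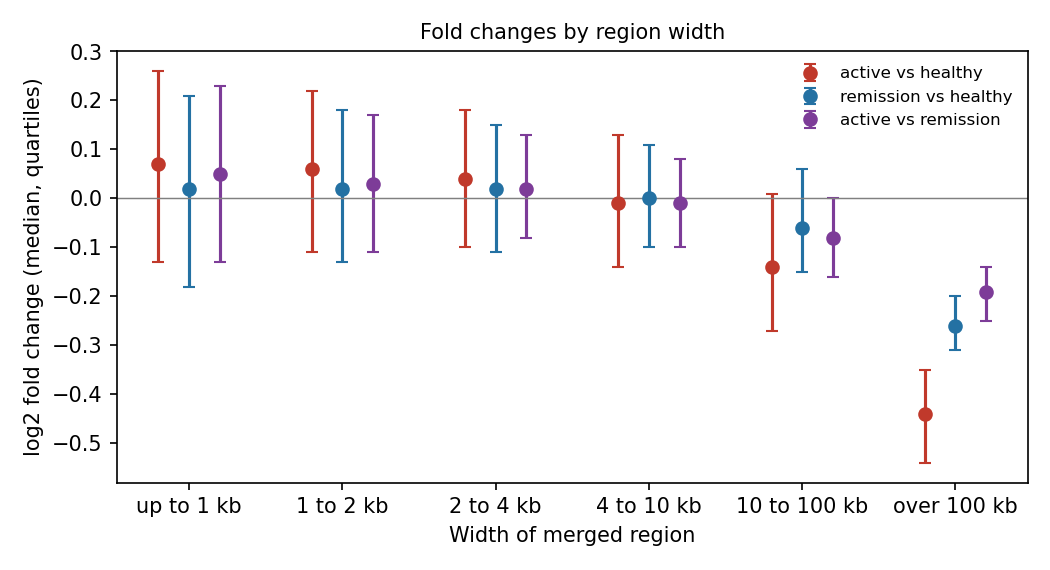
Median log2 fold change (y axis; bars are quartiles over regions) by width of the merged region (x axis) in active vs healthy, remission vs healthy and active vs remission. In regions over 100 kb the medians were -0.44, -0.26 and -0.19.

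Measured per library, regions over 100 kb took 38.5% ± 4.78 of autosomal counts (SD, n = 6) in healthy, 31.9% ± 4.04 (n = 5) in active and 34.3% ± 5.3 (n = 5) in remission libraries. Active libraries were lower than healthy ones with an exact two-sided permutation p of 0.0455, which was 0.221 after adjustment over 18 measures, so the difference did not pass. The difference was -6.6 percentage points, and 3 of 5 active libraries lay below every healthy one. Within the 3 lanes that hold an active and a healthy library the active library was lower in all 3, by a mean of -10.1 points. For remission vs healthy the exact p was 0.193 (mean within 3 lanes -3.6), for active vs remission 0.46 (mean within 2 lanes -3.68), and for patients vs healthy 0.046 (adjusted 0.323; mean within 6 lanes -6.86). Without the 3 libraries with few high-scoring peaks the active difference was -4.91 (exact p = 0.143), and it missed 0.05 in 8 of 11 fits that each left out 1 library, with a range of -8.07 to -5.51.

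Regions of at most 2 kb took 5.21% ± 0.602 of counts in active and 4.21% ± 0.584 in healthy libraries (exact p = 0.0281, adjusted 0.221), with a mean difference of 1.41 points within 3 lanes. The count density of recurrent high-scoring regions over background was 1.72 ± 0.3 (SD, n = 6) in healthy, 1.37 ± 0.254 (n = 5) in active and 1.67 ± 0.134 (n = 5) in remission libraries. Active libraries were lower than remission libraries at an exact p of 0.0476 (adjusted 0.857; mean within 2 lanes -0.501), and lower than healthy ones at an exact p of 0.0693 (adjusted 0.221; mean within 3 lanes -0.339). The share of counts within 2 Mb of a chromosome end was 1.98% ± 0.28 in healthy, 2.39% ± 0.329 in active and 2.3% ± 0.441 in remission libraries (active vs healthy exact p = 0.0541, adjusted 0.221; mean within 3 lanes 0.639). Reads not aligned made up 1.6% ± 0.153 in healthy and 1.35% ± 0.209 in active libraries (exact p = 0.0433, adjusted 0.221; mean within 3 lanes -0.353), and reads of low mapping quality 15.9% ± 1.18 and 14.1% ± 1.66 (exact p = 0.0736, adjusted 0.221; mean within 3 lanes -3.13).

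**Figure D3:**
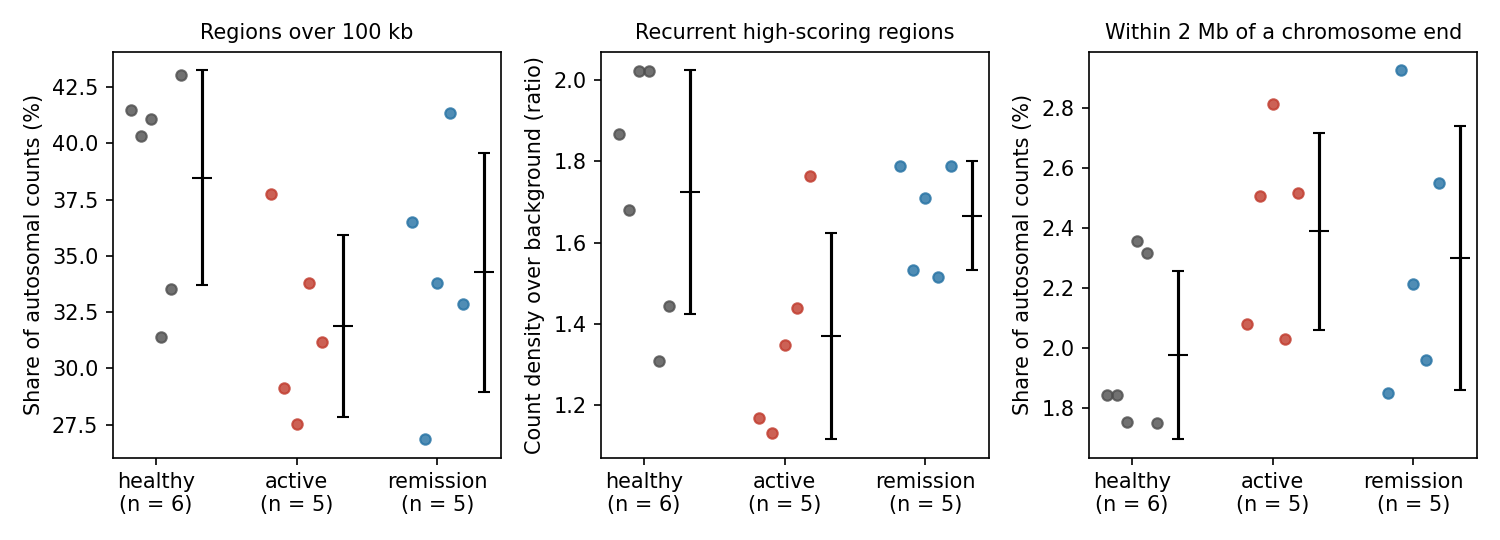
Share of autosomal counts in regions over 100 kb (left, %), count density of recurrent high-scoring regions over background (middle, ratio) and share of counts within 2 Mb of a chromosome end (right, %) in 6 healthy, 5 active and 5 remission libraries; points are libraries, and the bar beside each group is the mean with SD. The groups overlapped in every panel, with wide-region means of 38.5%, 31.9% and 34.3%.

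Whole chromosomes showed the same kind of shift without passing a test. Chromosome 22 took 0.851% ± 0.177 of counts (SD, n = 5) in active and 0.664% ± 0.145 (n = 6) in healthy libraries, a log2 difference of 0.36. The differences were 0.21 for chromosome 20, 0.17 for chromosome 19, -0.11 for chromosome 4 and -0.13 for chromosome 13. The smallest adjusted p over 22 chromosomes was 0.25 in active vs healthy, 0.575 in remission vs healthy, 0.952 in active vs remission and 0.266 in patients vs healthy (exact permutation tests). Across chromosomes, which are not independent replicates, the log2 differences followed GC content with r = 0.89 (rho = 0.91) in active vs healthy and r = 0.94 (rho = 0.89) in remission vs healthy.

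**Figure D4:**
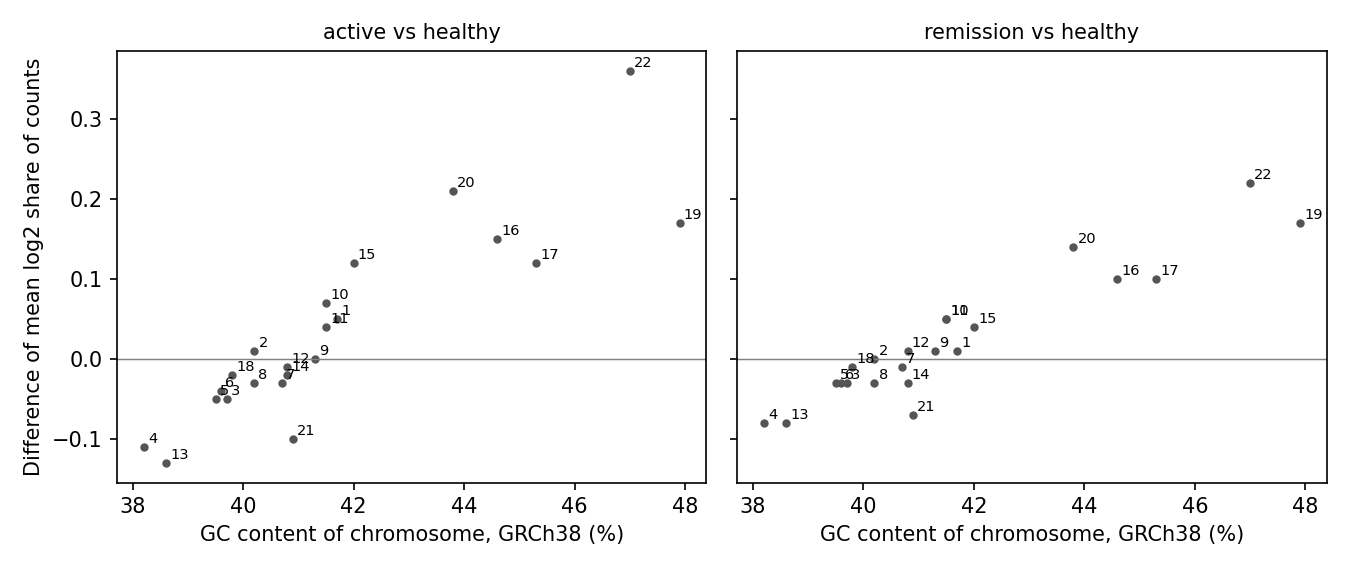
Difference of the mean log2 share of counts per autosome (y axis) against the chromosome's GC content in GRCh38 (x axis, %), for active vs healthy (left) and remission vs healthy (right); each point is a chromosome. Chromosome 22 had the largest positive difference in active vs healthy (0.36) and chromosome 13 lay at -0.13; no chromosome passed the adjusted test.

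Across all 16 libraries the first principal component held 25.4% of the variance and followed the share of counts in regions over 100 kb, with r = -0.84 (permutation p = 9e-05, adjusted p = 0.00045 over 5 relations) and rho = -0.85 (permutation p = 7e-05). Without the 2 libraries farthest from the median r was -0.86.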

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

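All tests of explanations in this part, with their bounds, were chosen after the results were seen. The comparisons of wide-region shares and the lane block were also chosen then.

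In 10 of 159 tests, a library stood far from the others of its group, measured by the gap to its nearest neighbour over the group's range; chance gives about 8, so these carry little weight. Remission 4 had the fewest peaks of its group, 0.742 against 1.44 to 1.7 (in units of 1e6), and the widest flanks, 1160 bp against 270 to 410 bp. It is 1 of the 3 libraries with few high-scoring peaks. At chromosome 7 (155940561 to 155942810) healthy 1 lay at 0.63 normalised CPM, below 0.78 to 0.86 in the other healthy libraries. At chromosome 12 (132163117 to 132170836) active 1 lay at 2.09, below 3.54 to 3.94. At chromosome 9 (177805 to 180934) healthy 4 lay at 1.26, above 0.782 to 0.91. At chromosome 14 (65330411 to 65334500) remission 1 lay at 0.913, below 1.26 to 1.39. At chromosome 10 (38944226 to 38950505) active 3 lay at 1.05, below 1.57 to 1.68. Healthy 4 gave 9.58% of its counts to chromosome 1, above 8.77% to 9.06%, healthy 5 gave 9.73% to chromosome 2, below 9.95% to 10%, and healthy 1 gave 2.74% to chromosome 14, below 2.85% to 2.89%.

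Regions over 100 kb took a lower share of counts in active than in healthy libraries, a difference of -6.6 percentage points that did not pass adjustment. The tables argue against depth as the cause, since the difference was -6.83 with log2 depth in the model. Against the lane as the whole cause, the mean within 3 lanes was -10.1 (-13.9 to -6.49, lower in 3 of 3), as far as 1 read name per file gives the lane. These lanes hold healthy 1, 2 and 3, with shares of 41.5%, 40.3% and 41.1%. The lowest healthy libraries, 4 and 5 (31.4% and 33.5%), lie in other lanes. With 3 pairs a part of the lane is therefore not excluded. Base composition of the fragments and an opening of gene-rich against gene-poor chromatin in active disease both stay open and cannot be told apart: slopes of chromosome shares on GC content differed with an exact p of 0.141 and on gene density with an exact p of 0.173. Differences across chromosomes followed GC content with r = 0.89 and gene density with r = 0.72, which themselves correlate at 0.91. The part of a chromosome in regions over 100 kb correlates with them at -0.79 and -0.67, so these relations may partly restate the wide-region difference. With the other held, the slope difference was 0.15 on GC content (exact p = 0.0866) and -0.053 on gene density (exact p = 0.104), the latter opposite to an opening of gene-rich chromatin but without passing. A shift in library quality may also contribute, since the difference was -4.91 (exact p = 0.143) without the 3 libraries with few high-scoring peaks. The same removal enlarged the difference in remission vs healthy, from -4.2 to -5.37 (exact p = 0.127). By the labels both patient groups were on treatment or medication. In comparisons with healthy libraries, treatment therefore cannot be told apart from disease, and it was not tested.

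The chromosome 10 region (51937261 to 51957570) was lower in patients, and 2 explanations were tested. The tables argue against the lane as the whole cause, since with lane as a block the log2 fold change was -3.63 (edgeR adjusted p = 0.000145) in place of -3.39, as far as 1 read name per file gives the lane. The region's count density was 3.17% of that of regions of 15 to 25 kb in healthy libraries and 0.36% in patients; how well reads can be placed there was not measured, so reads shared between copies of the sequence were not tested. Donor variants against the reference cannot be told apart from an effect of disease or of its treatment. Regions are not independent and no donor sequence was used. All healthy were parted from all patient libraries with healthy higher at 35 regions, where chance gives 29.5, and at 77 the other way. Of the 3 nearest regions on either side, log2 ratios of patients over healthy were -0.58, -0.16 and 0.12 before it, the last at only 0.0519 and 0.0477 CPM, and 0.15, -0.09 and -0.02 after it.

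With lane as a block, active vs healthy gave 8408 calls in place of 1. If libraries of a lane deviated together, lane-mates would correlate more than other libraries; their mean correlation was 0.08 against -0.01, with a one-sided permutation p of 0.1, and single pairs ranged from -0.22 to 0.45, with 3 of 8 above 0.1. Among 20 random re-pairings of libraries with the same structure, 1 gave as many calls in active vs healthy (highest 26563, median 2.5), 0 in active vs remission (highest 1340 against 1532), 1 in patients vs healthy (highest 13102 against 562) and 14 in remission vs healthy (highest 15 against 2). A lane effect therefore stays open, and no biological explanation of the added calls was tested.

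Other splits of the 16 libraries into groups of the same sizes were fitted in edgeR, 50 with the real one. In active vs healthy, 1 split, the real one, gave 1 call or more (real value 1, highest other 0), which is under the 5% limit. Of 20 simulations of unchanged groups, however, 1 also gave a call in this comparison (highest 1). Chance is therefore not excluded for that count. The count rests on a single region, and no adjustment was made for the 4 comparisons. With the real split included each time, in remission vs healthy 3 splits gave as many as the real 2 (highest other 15252), in active vs remission 50 gave as many as the real 0 (highest other 22181), and in patients vs healthy 3 gave as many as the real 1 (highest other 1), so chance cannot be excluded there. More than 100 calls came from 1 other split in remission vs healthy, 2 in active vs remission and 0 in the other comparisons; such splits point to a structure of the samples, and what it is was not tested. At an unadjusted p under 0.05, 4 splits (the real one included) gave as many regions as the real 26946 in active vs healthy, 11 in remission vs healthy, 33 in active vs remission and 2 in patients vs healthy. The counts by DESeq2, limma-voom and the lane block were not tested on other splits.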

How the results depend on the processing

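The settings with lane, recurrent regions, region width or density covariates were chosen after seeing the data. So were those without the 3 libraries with few high-scoring peaks or without the 3 with a further file suffix. All shares, signal and distal measures were also chosen then. The rest, apart from flank width, were fixed before the data were examined. No paired analysis was possible because replicate numbers were given in order of accession and pair no libraries; libraries that share a lane were instead fitted with lane as a block. A promoter covariate, GC offsets, and gene, list and motif tests were not run, since no hg19 annotation was used. Of the values of named regions under other settings, 665 kept their sign and side of the threshold, 46 came to pass it, 9 no longer passed, and none changed sign. The naming rule required the same sign in each of the 16 fits that leave out 1 library. For those fits the kept sign was therefore fixed in advance. Where a count below moved, the cause was not tested, apart from the fewer regions or libraries that a setting holds by construction. In simulated data 12% of regions changed 1.5-fold and 69% of those changed 2-fold were recovered, beside 9 false calls in active vs healthy and 11 in remission vs healthy; whether depth (median count 132) or the spread between donors (18.8%) set this limit was not tested.

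Counts of regions past the threshold are given for active vs healthy, remission vs healthy, active vs remission and patients vs healthy, in edgeR 1, 2, 0 and 1. DESeq2 gave 3320, 4, 1 and 19. Limma-voom gave 264, 2, 0 and 4. Library size alone gave 0, 0, 0 and 1. A mean count of at least 30 gave 0, 1, 0 and 0. Lane as a block gave 8408, 2, 1532 and 562. Regions with a recurrent high-scoring peak gave 0, 0, 0 and 0, both with and without the 2 density covariates. Regions of at most 10 kb gave 0, 1, 0 and 0, and those of them with a recurrent high-scoring peak 4, 3, 0 and 5. The wide-region density as a covariate gave 0, 1, 0 and 1. Without the 3 libraries with few high-scoring peaks the counts were 2, 2, 0 and 1. Where edgeR gave 0, regions with an unadjusted p under 0.05 in active vs healthy numbered 52502 with library size, 26429 with the mean count, 3196 in recurrent regions (801 with covariates), 17955 up to 10 kb and 11927 with the wide-region covariate; in remission vs healthy 16577 with library size and 965 (619) in recurrent regions; in patients vs healthy 25483 with the mean count, 2636 (840) in recurrent regions and 18634 up to 10 kb; in active vs remission 7102 with library size and 8975 with the wide-region covariate. RLE size factors, loess offsets, no filter, all chromosomes and 1 surrogate variable each gave 1, 2, 0 and 1, and fitting only the groups compared gave 1, 3, 0 and 1. Leaving out 1 library gave 1 to 1121, 1 to 4, 0 to 1 and 1 to 24, with 1121 and 24 both without healthy 5. The number of shared calls was 0 in the median split of the healthy libraries.

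No permutation p of a measure of peaks was under 0.05 in any of 148 settings (smallest 0.0571). Peaks of score 20 or more differed by -1.96 (in units of 1000) in active vs healthy. A further suffix marks the peak files of active 1, active 5 and remission 5 and of no healthy library, so it falls in the patient groups alone. Without the 3 libraries with a further file suffix, open width differed by -226 bp in active vs remission (exact p = 0.286) and -302 bp in active vs healthy (exact p = 0.202; -10.3 with all libraries), and flank width by 30 bp in active vs healthy and 42.5 bp in remission vs healthy. Flanks of the 100000 highest peaks differed by 76 bp in remission vs healthy. An overlap of at least 50% of both peaks gave -0.322 points within minus between groups. Leaving out 1 library, these ranged from -0.0995 to 0.135, 0.113 to 0.398 and -0.375 to -0.0998 (in units of 1e6) for peaks, from -178 to 104, -126 to 79.2 and -150 to 132 bp for open width, from -82.5 to 66, -180 to 86 and -76.5 to 146 bp for flanks, in active vs healthy, remission vs healthy and active vs remission, and from -0.576 to 2.09 points for overlap.

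Without the 3 libraries with few high-scoring peaks, the wide-region difference was -4.91 in active vs healthy and -5.37 in remission vs healthy. It was 0.454 in active vs remission and -5.14 in patients vs healthy. In the same setting the signal difference was 0.00911 in remission vs healthy and -0.329 in active vs remission, and the distal difference -0.101 in active vs remission. The distal difference within 5 Mb was 0.992 in active vs healthy (exact p = 0.0476). Within 1 Mb the exact p was 0.0844. In regions of at most 10 kb it was 0.149, 0.0736 and 0.0801 within 1, 2 and 5 Mb. Leaving out 1 library, in active vs healthy, remission vs healthy, active vs remission and patients vs healthy, wide-region differences ranged from -8.07 to -5.51, -5.97 to -2.34, -4.26 to -0.631 and -6.81 to -4.48, signal differences from -0.452 to -0.294, -0.141 to 0.00205, -0.395 to -0.236 and -0.289 to -0.146, and distal differences from 0.306 to 0.501, 0.166 to 0.435, -0.0233 to 0.246 and 0.303 to 0.443.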

Other observations

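The distance of the named regions from chromosome ends was tabulated after seeing the data. In the comparisons with healthy libraries, 5 named regions were higher in patients, of which 4 lay within 5 Mb of a chromosome end, at 0.78 and 1.24 Mb on chromosome 5, 1.68 Mb on chromosome 12 and 3.2 Mb on chromosome 7. Among the 7 named regions that were lower, 1 did, at 0.18 Mb on chromosome 9, and 10.7% of all autosomal regions do. In active vs remission the 3 higher regions lay 68.52, 41.95 and 11.19 Mb from an end, and of the 3 lower ones 1 lay within 5 Mb, at 4.29 Mb. Of the higher regions only that at 0.78 Mb passed the threshold, in remission vs healthy, and of the lower ones only that on chromosome 10 at 51.94 Mb. The regions were picked for their small p, so no test was made of the placement and nothing is said of other regions.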
